A study of Mus musculus with 2 samples.

How the data were processed

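RNA was sequenced from bone marrow-derived macrophages of C57BL/6 mice, 1 library from wild-type cells (WT) and 1 library from cells that carry the T403A substitution in STAT2. Per the labels' protocols, marrow cells of 8-week-old animals were cultured for 7 days with M-CSF, the growth factor that drives marrow progenitors to become macrophages, and received no treatment (the libraries are labelled 0 h). Total RNA was isolated with TRIzol, treated with DNase I, and 1 μg was sequenced on an Illumina HiSeq instrument, per the labels' protocols.

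The deposited table holds whole-number read counts per Ensembl gene, per the file headers, with 1 column per library and a gene length in bases. The submitters' processing notes name cutadapt 1.15, HISAT2, HTSeq 0.9.1, DESeq 1.30.0 and the genome build GRCm38. The role of each tool, the annotation release, the strand setting and how RNA was selected before library preparation are not given in the sources used here. Because the strand setting is unknown, reads of overlapping genes on opposite strands cannot be told apart, and counts of near-identical family members (the Ifi200, Oas1, Ly6, Slfn, Gbp and H2-Q families) depend on how multiply mapped reads were treated. Besides the genes for which the text says so, several more have exons that overlap those of another annotated gene. On the opposite strand these are Rnf213, Usp18, Ptpn6, Ikbke, Il1a, Mmp12, Tgm2, Ctsb, Aldoa, Ms4a6c, Fbn1, mt-Nd5, mt-Co1, Atp5a1 and Apobec3. Their counts carry the same limit. On the same strand these are Nr1h3, Pkm, Rpl10, Rpl13a, Snhg11 and again Apobec3, where a strand setting would not separate the reads. Columns were matched to the samples by title. The table has 22060 genes, of which 21969 were given a symbol from a table of Ensembl identifiers. Of 2 identifiers that share a symbol, the one with more counts kept it. Gene positions come from GENCODE M21, which is on the same build. The deposited gene length equalled the union of the M21 exons for 96.8% of genes. No column of per-sample values was left unused.

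The count total was 16033032 in the WT library and 18658381 in the T403A library. Each group is a single library, so no difference has a replicate check, no p-value is given, and every statement compares these 2 libraries and not the genotypes. Counts were scaled with TMM (edgeR 4.0.16 in R 4.3.3) and are given as CPM, the usual unit of counts relative to the scaled library total. The T403A to WT ratio of each gene carries an exact 95% interval (Clopper-Pearson on the 2 counts, scipy 1.17.1). Intervals and floors cover counting error only. Variation between animals, cultures and library preparations is not in them. A count of 0 allows up to 3 counts, which is 0.20 CPM in the WT library and 0.15 CPM in the T403A library. Where a library had a count of 0, the fold was computed against 3 counts in that library, with the other count taken as it stands. The exact 95% interval, which also allows for error in the other count and was used for the ranking, has a lower bound nearer to 1: 34.9-fold for Kif14, 12.1-fold for Depdc1b, 71.0-fold for Tmeff1, 53.0-fold for F830016B08Rik, 26.0-fold for Apol9b and 6.92-fold for Cfb.

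The 11199 genes with a summed count of at least 20 were treated as measured. A gene was counted as higher or lower when the ratio was at least 2-fold and its interval excluded 1. Members of gene lists were counted at 1.5-fold with the same condition. In total, 34 lists were written before the data were examined: 19 of pathways or functions, 9 of cell types, 3 of RNA quality or RNA selection, and 3 for sex chromosome genes, neighbours of Stat2 and genes that vary between mouse substrains. For each list the median log2 ratio (prior count 0.5 per library) was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. Medians with genes at a count of 0 set to their bound were equal to those given. The percentile describes the 2 libraries and is not a test across replicates. The genes named in the text were chosen by a rule fixed before the data were examined: Stat2, the 12 highest and the 12 lowest genes with a mean of at least 1 CPM, ranked by the interval bound nearest to 1, and from each list up to 4 members (the 2 with the largest ratio and the 2 with the highest count). Predicted gene models, RIKEN clones, genes without a symbol and pseudogenes were counted but not named among the highest and lowest. Some listed genes are not reported here by name. Members beyond this rule that are named as illustrations were chosen after their values were seen.

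The scoring was tested on simulated libraries drawn from the mean profile and totals of these libraries, with 200 genes changed by known folds. These genes had an expected summed count of at least 100 and were all raised in T403A. Changes in weaker genes and lowered genes were therefore not tested. Library totals were used for scaling in place of TMM. With counting noise alone, 100% of genes changed 3-fold were called 2-fold apart, none of those changed 1.5-fold was, and 25 of 10991 unchanged genes were called. With an assumed coefficient of variation of 0.2 between libraries, 275 of 10970 unchanged genes were called together with 88.0% of those changed 3-fold, and with 0.4, 2542 of 10933. With counting noise alone the interval held the true ratio for 95.3% of unchanged genes.

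The alternatives were total library size, DESeq2 1.42.0 size factors, upper quartile scaling, scaling on totals without the 20 most abundant genes and the mitochondrial genes, other count minimums (none and 100), thinning of the deeper library, other fold thresholds, other prior counts, and intervals widened by an assumed coefficient of variation of 0.1, 0.2 or 0.4. Centring of the ratios within bins of expression was added after the data were seen.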

Results

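The series compared the transcriptomes of unstimulated M-CSF macrophages from WT mice and from mice with a STAT2 in which threonine 403 is replaced by alanine. STAT2 is a subunit of the transcription factor complex activated by type I interferon, and the comparison shows how the libraries differ before any stimulus. One library was available per genotype, with 16033032 counts for WT and 18658381 for T403A. At least 1 count was found for 13205 genes in the WT library and for 13547 in the T403A library. The 20 most abundant genes took 16.3% of the WT counts and 15.4% of the T403A counts. Transcripts of the mitochondrial genome made up 1.93% of counts in the WT library (95% Wilson interval 1.92 to 1.94) and 2.46% in the T403A library (2.45 to 2.46).

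The targeted gene itself was lower in the T403A library. Stat2 (ENSMUSG00000040033, chromosome 10, 128270559 to 128292849 on the plus strand, GRCm38, protein-coding) was at 376 CPM in WT and 84.4 CPM in T403A, a 4.46-fold difference (95% counting interval 4.22 to 4.71). A substitution of 1 amino acid need not change a gene's read count, so this value does not check the labels. Both libraries held reads of all 4 Y-linked genes examined. Ddx3y was at 53.7 CPM in WT and 69.3 in T403A, Kdm5d at 30.5 and 35.5, and Eif2s3y at 49.5 and 49.9. Uty was at 24.3 CPM in WT and 27.6 CPM in T403A. None of these 4 genes differed by 1.5-fold.

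Interferon-stimulated genes were lower and mitotic genes higher in the T403A library. Of the 11199 measured genes, 808 were at least 2-fold higher and 681 at least 2-fold lower in T403A, with counting intervals that excluded 1. In the simulation, 275 of 10970 unchanged genes were called with an assumed coefficient of variation of 0.2. With 0.4, 2542 of 10933 were called, so the counts alone do not show how many genes differ between cultures. Scaling by total library size moved the median log2 ratio of all genes by 0.19, and the split was then 1122 higher and 560 lower. Across genes, log2(CPM + 1) of the libraries had a Pearson correlation of 0.95, where genes are not independent replicates. Among the 8182 genes with a mean of at least 10 CPM, 249 were higher and 445 lower.

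Of the 12 lowest named genes in T403A, 6 were on the list of interferon-stimulated genes fixed beforehand (Oasl1, Ifi44, Ifi213, Ly6a, Slfn1 and Oas1g). Oasl1, a 2'-5'-oligoadenylate synthetase-like protein on chromosome 5 (114923240 to 114937915), was at 111 CPM in WT and 0.853 in T403A, 131-fold lower (interval 81.4 to 225). A limit is that an unlisted gene model overlaps its exons on the opposite strand. Ifi44 (chromosome 3, 151730922 to 151749960) was 98.8-fold lower (63.8 to 162) and Oas1g 42.0-fold lower (31.2 to 57.9). In the Ifi200 cluster on chromosome 1, Ifi213 was 57.9-fold, Ifi208 51.4-fold and Ifi206 47.5-fold lower, where similar family members can share reads. Slfn1, of the Schlafen family, was 63.8-fold lower, and the Ly6 family surface proteins Ly6i and Ly6a were 107-fold and 51.2-fold lower. The chemokine Ccl5 was at 169 CPM in WT and 4.41 in T403A, 38.3-fold lower (31.0 to 48.0). Outside these families, Cav1, which encodes the caveolar coat protein caveolin-1, was 47.5-fold lower (35.1 to 65.9). Tmeff1 had 199 counts in WT and 0 in T403A, 88.2-fold lower against 3 counts (exact lower bound 71.0-fold).

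Of the 12 highest named genes in T403A, 3 were on the cell cycle list (Cenpf, Ccna2 and Birc5), and others encode mitotic proteins. Cenpf, a kinetochore protein on chromosome 1 (189640606 to 189688086), was at 0.600 CPM in WT and 34.0 in T403A, 56.7-fold higher (29.7 to 124). Aspm, which organises spindle poles (chromosome 1, 139454772 to 139494091), was 24.7-fold higher (15.7 to 41.3). Ccna2, the cyclin of S phase and mitotic entry, was 21.2-fold higher (13.5 to 35.5), with the limit that its exons overlap those of Exosc9 on the opposite strand. Birc5 (survivin) was 27.7-fold higher and the mitotic kinesin Kif2c 27.6-fold higher. Spag5, Anln and Prr11 were 21.1-fold, 17.4-fold and 22.7-fold higher. Pimreg and the DNA glycosylase gene Neil3 rested on 4 WT counts each and were 39.3-fold higher (15.1 to 146) and 32.9-fold higher (12.6 to 122). The kinesin Kif14 had 0 counts in WT and 173 in T403A, 43.4-fold higher against 3 counts (exact lower bound 34.9-fold). Depdc1b had 0 and 61 counts, 15.3-fold higher against 3 counts (exact lower bound 12.1-fold).

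**Figure D1:**
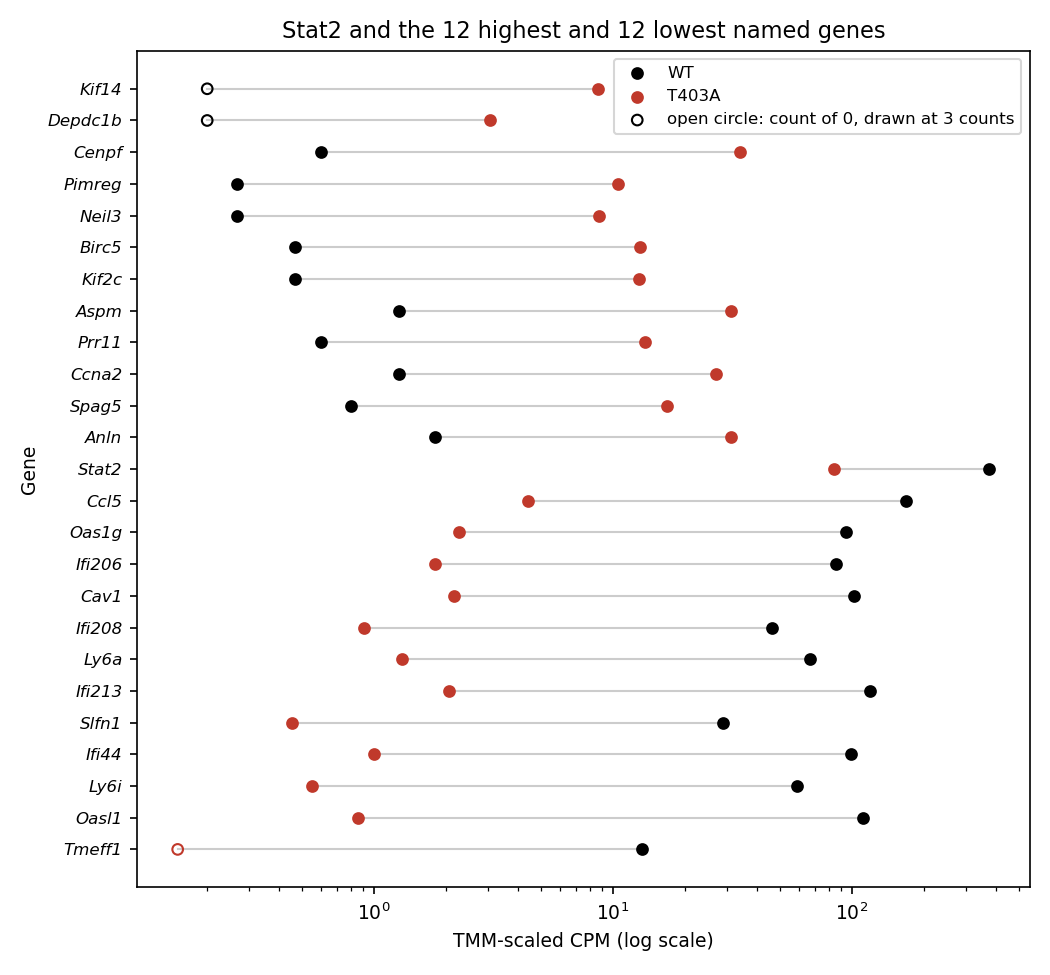
Expression of Stat2 and of the 12 highest and 12 lowest named genes, as TMM-scaled CPM on a log axis, with 1 point per library (black for WT, red for T403A). An open circle stands for a count of 0 and is drawn at the level of 3 counts, as for Kif14 with 173 counts in T403A. Stat2 was at 376 CPM in WT and 84.4 CPM in T403A.

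Genes induced by type I interferon were lower in T403A almost without exception. Of the 92 measured members of this list, 91 were at least 1.5-fold lower, none was higher, and 1 met neither condition (Trim21, log2 ratio -0.51). As many expression-matched genes would include 12.9 lower ones. The median member was 6.81-fold lower (median log2 ratio -2.77), below every one of the 10000 random lists, whose central 95% ran from -0.15 to 0.04. Together the listed genes took 2.65% of WT counts (95% Wilson interval 2.64 to 2.66) and 0.546% of T403A counts (0.542 to 0.549). Among the abundant members, the ubiquitin ligase gene Rnf213 was 5.11-fold lower and Ly6e 4.84-fold lower. Apol9b had 74 counts in WT and 0 in T403A, 32.8-fold lower against 3 counts. F830016B08Rik, an interferon-inducible GTPase gene, had 149 and 0, 66.0-fold lower against 3 counts. The exact lower bounds of both genes are smaller folds and are given with the processing.

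Genes of the interferon-gamma list were mostly lower as well. Besides guanylate-binding proteins and immunity-related GTPases, the list holds other genes such as Irf8 and Icosl. In this list 20 of 27 measured genes were lower, 1 was higher (Icosl, log2 ratio 0.79) and 6 met neither condition, with a median 3.72-fold lower. Gbp6, whose exons overlap those of another listed gene model on the same strand, was 21.5-fold lower, Iigp1 14.8-fold lower and Irgm1 5.14-fold lower. Irf8 was at 289 CPM in WT and 259 CPM in T403A, within 1.5-fold. The interferon signalling list holds receptor, kinase, STAT and IRF genes and others such as Usp18 and Ptpn6. Of its 34 measured genes, 15 were lower, 1 was higher (Irf4, log2 ratio 0.84) and 18 met neither condition. Irf7, the factor that amplifies interferon production, was at 581 CPM in WT and 18.4 CPM in T403A (31.6-fold lower), with the limit that its exons overlap those of Phrf1 on the opposite strand. The feedback inhibitor Usp18 was 14.5-fold lower and the kinase Ikbke 1.84-fold lower, while the phosphatase Ptpn6 was within 1.5-fold at 449 and 360 CPM. The median of this list was -0.42, below every random list.

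Antigen presentation genes were lower in T403A. In the class I list 21 of 25 measured genes were lower and none was higher, with a median 2.26-fold lower. B2m, the invariant light chain, was 2.56-fold lower, H2-D1 1.59-fold, and the nonclassical H2-Q7 21.3-fold lower. H2-Q6 was at 56.5 CPM in WT and 2.46 CPM in T403A, where near-identical copies make the split between members uncertain. In the class II list 8 of 14 were lower and none higher, with a median 2.27-fold lower. With no count filter its median log2 ratio was -0.68 over 15 genes, against -1.18 over the 14. The costimulatory ligand Cd86 was 5.86-fold lower, and H2-Ob, on 28 and 4 counts, was 9.30-fold lower. The protease Ctss was 1.60-fold lower, and Lgmn was within 1.5-fold at 978 and 699 CPM. The class I and class II medians both lay below every random list.

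**Figure D2:**
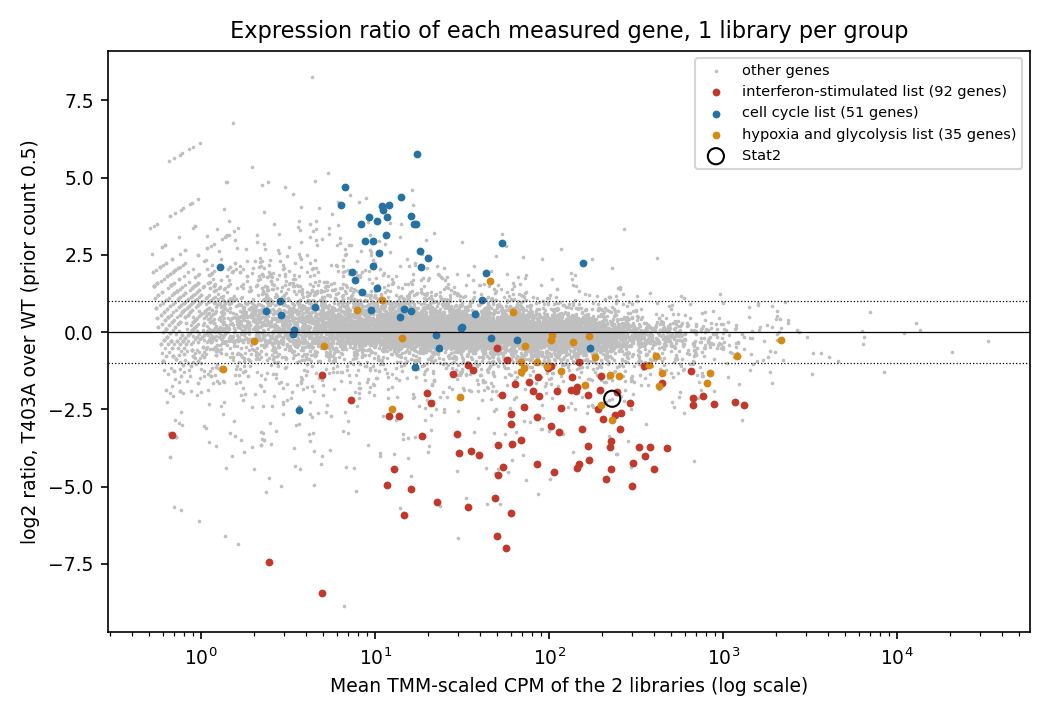
The log2 ratio of T403A over WT for each of the 11199 measured genes against mean TMM-scaled CPM on a log axis, with dotted lines at a 2-fold difference. Of the interferon-stimulated list (red) 91 of 92 genes were at least 1.5-fold lower in T403A, of the cell cycle list (blue) 38 of 51 were at least 1.5-fold higher, and of the hypoxia and glycolysis list (orange) 22 of 35 were at least 1.5-fold lower.

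Cell cycle genes were higher in T403A. Of 51 measured genes 38 were at least 1.5-fold higher, 2 were lower and 11 met neither condition. As many expression-matched genes would include 9.43 higher ones. The median member was 3.85-fold higher (median log2 ratio 1.95), above every random list. The proliferation marker Mki67 was at 54.8 CPM in WT and 258 CPM in T403A, 4.70-fold higher (log2 interval 2.13 to 2.34). Pcna, the replication clamp, was within 1.5-fold at 202 and 143 CPM. The 2 lower members were the D-type cyclin genes Ccnd1 (log2 ratio -1.14) and Ccnd2 (-2.56). The listed genes together took 0.0684% of WT counts (0.0671 to 0.0697) and 0.163% of T403A counts (0.161 to 0.165).

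In the list of inflammatory and NF-kB genes, 26 of 43 measured members were lower in T403A and none was higher. Its median was 1.72-fold lower, below every random list. Whether NF-kB activity differed was not tested. Acod1, which makes itaconate, was 7.14-fold lower, and the lectin receptor Clec4d 1.61-fold lower. Il1a had 69 and 2 counts, a 45.9-fold difference (log2 interval -8.59 to -3.61). Il1b was lower by a log2 ratio of -4.44, while Tnf (-0.46) and Nfkbia (-0.38) were within 1.5-fold. Immediate early genes were lower in 15 of 26 and higher in 1 (Klf4, log2 ratio 0.75), with a median 1.87-fold lower, below every random list. Fos was 4.23-fold lower, Egr3 4.43-fold lower and Nr4a2 14.6-fold lower, and Klf6 was within 1.5-fold at 568 and 430 CPM. Of 28 pattern recognition genes 10 were lower and 2 higher (median log2 ratio -0.36, percentile 0.05). The RNA sensor genes Ddx58 and Ifih1 were 6.08-fold and 3.63-fold lower and the lipopolysaccharide co-receptor gene Cd14 3.21-fold lower. Unc93b1, which carries endosomal Toll-like receptors, was 1.40-fold lower and met neither condition.

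Genes of hypoxia and glycolysis were lower in 22 of 35 measured members and higher in 4, with a median log2 ratio of -0.97, below every random list. The lactate exporter Slc16a3 was 7.10-fold lower, the oxygen-sensing hydroxylase gene Egln3 5.69-fold lower and the glycolytic enzyme gene Aldoa 1.71-fold lower. Pkm was within 1.5-fold. The 4 higher members were Ndrg1 (log2 ratio 1.67), Slc2a3 (1.06), Eno2 (0.70) and Aldoc (0.65). Nuclear-encoded subunits of the respiratory chain were not shifted: 32 of 33 met neither condition, with a median log2 ratio of 0.06 inside the random range of -0.18 to 0.12. Cycs was the 1 lower gene, by 2.01-fold, and Atp5a1, Atp5b and Ndufa1 were within 1.5-fold.

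Complement genes were lower in 10 of 15 measured members and higher in 1, with a median 2.03-fold lower, below every random list. C3, the central component, was 3.14-fold lower, C1qb 2.03-fold lower and C4b, on 47 and 5 counts, 12.5-fold lower. Cfb had 21 counts in WT and 0 in T403A, 9.30-fold lower against 3 counts (exact lower bound 6.92-fold). A limit is that its exons overlap those of another listed gene model.

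Markers of macrophage identity went both ways. Of 29 measured genes 11 were lower, 3 were higher and 15 met neither condition, with a median log2 ratio of -0.40 (percentile 0.67). The abundant lysozyme gene Lyz2 was within 1.5-fold in the libraries. The Fc receptor gene Fcgr1, which is also on the interferon-stimulated list, was 8.76-fold lower, Gpnmb was 1.58-fold higher and the mannose receptor gene Mrc1 5.12-fold higher (57.5 and 295 CPM). Among 18 genes typical of interleukin-4 activation, 7 were lower and 4 higher, with a median log2 ratio of -0.43 (percentile 0.13). Arg1 (71 and 3 counts) was 31.5-fold lower (log2 interval -7.29 to -3.37), Tgm2 10.3-fold lower, Clec7a 1.63-fold lower and Mmp12 1.80-fold higher. Lysosomal genes had a median log2 ratio of 0.13, above 99.96% of the random lists, and at 1.5-fold 6 of 37 were lower and 4 higher. As many expression-matched genes would include 7.73 lower and 2.43 higher ones. Ctsc and Ctsh were 3.87-fold and 2.19-fold lower, and Psap and Ctsb were within 1.5-fold.

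Lists of lipid and stress metabolism had medians inside the random range, and the signs of the sterol, liver X receptor, stress and NRF2 medians changed with library size scaling. In sterol synthesis 3 of 24 genes were higher and 2 lower (median log2 ratio -0.08); Dhcr7 was 1.84-fold higher and Hsd17b7 2.53-fold lower, and Srebf2 was within 1.5-fold. In the liver X receptor list 4 of 21 were higher and 5 lower (-0.02); Apoe was 2.44-fold lower, Plin2 2.62-fold lower and the receptor gene Nr1h3 4.55-fold lower, while Lpl was within 1.5-fold. In the integrated stress and unfolded protein list 5 of 33 were higher and 5 lower (-0.04), with Gdf15 4.25-fold higher, Phgdh 3.66-fold higher, and Hspa5 and Edem1 within 1.5-fold. In the NRF2 list 2 of 22 were higher and 5 lower (-0.19), with Nqo1 2.05-fold higher, Slc7a11 2.19-fold lower, the ferritin gene Fth1 1.56-fold lower and Prdx1 within 1.5-fold. In the p53 list 3 of 19 were higher and 1 lower (0.09), with Gdf15 as above, Ckap2 19.3-fold higher, and Mdm2 and Sesn1 within 1.5-fold.

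**Figure D3:**
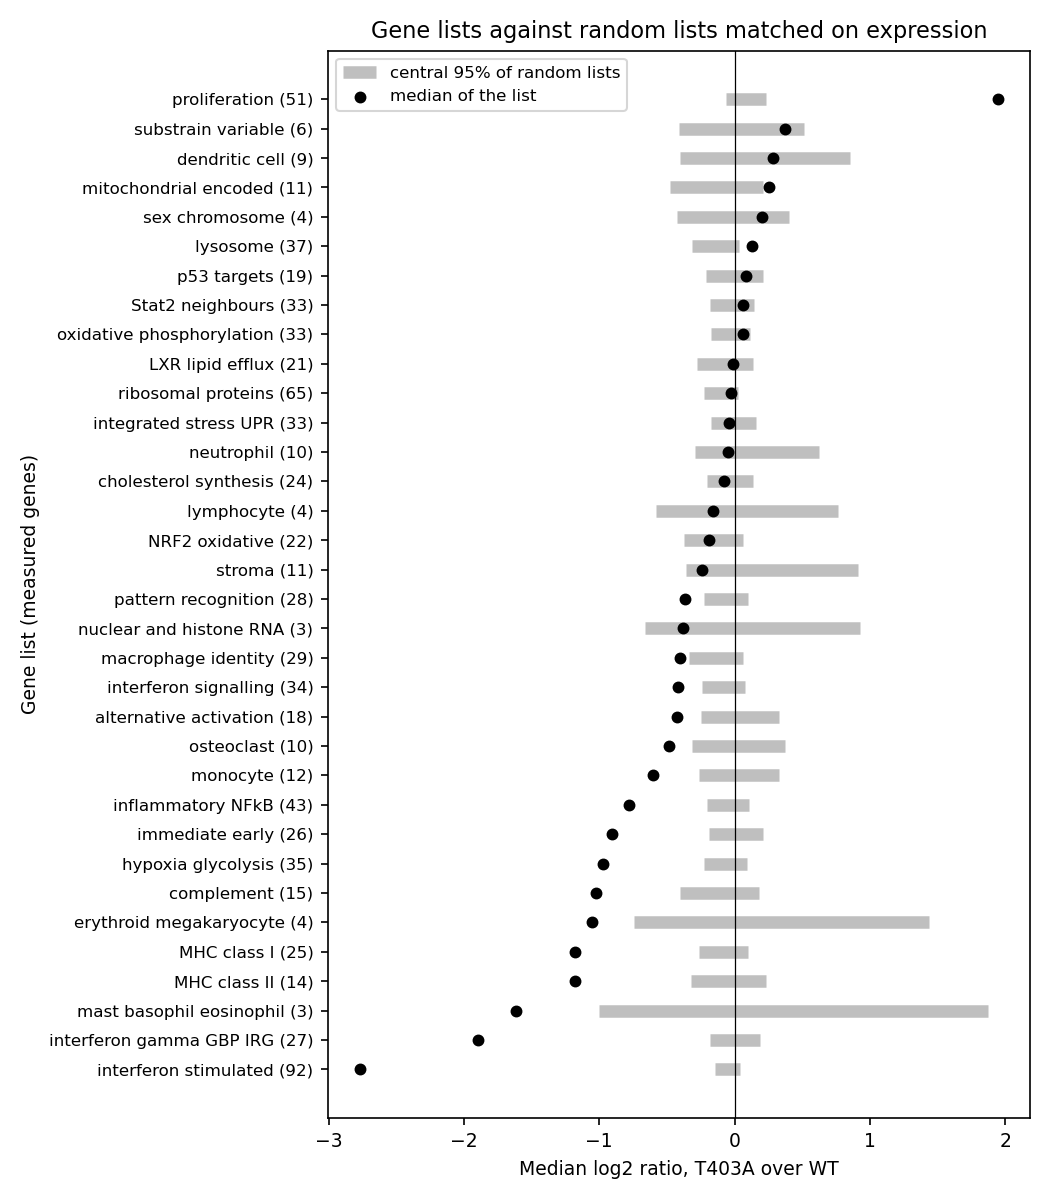
Median log2 ratio of T403A over WT for each of the 34 gene lists (points, with the number of measured genes in brackets) and the central 95% of 10000 random lists matched on expression (grey bars). The interferon-stimulated list lies lowest at -2.77 and the proliferation list highest at 1.95.

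Lists of other cell types that marrow cultures can hold had 3 to 12 measured genes each. The monocyte list was lower in 6 of 12 measured genes and higher in 1, with a median log2 ratio of -0.60 (percentile 0.02). In it Ly6c2 was 41.6-fold lower, Hp 9.12-fold lower and Ms4a6c 4.31-fold lower, while Mgst1 was within 1.5-fold. The osteoclast list had 4 of 10 lower and 3 higher (median -0.48, percentile 0.26), with Mmp14 15.2-fold lower, Itgb3 11.3-fold higher and Clcn7 within 1.5-fold. Of 10 measured neutrophil genes 4 were higher and 4 lower (median -0.05, 0.14 with library size scaling and 0.56 with no count filter). Mmp9, which the osteoclast list also holds, was 10.9-fold lower, Lcn2 9.36-fold lower, Csf3r 1.70-fold lower and Mmp8 3.19-fold higher. Of 9 dendritic cell genes 3 were higher and 3 lower (median 0.29), and Bst2, which the interferon-stimulated list also holds, was 5.60-fold lower. Fscn1 (20 and 3 counts) was 8.86-fold lower (log2 interval -5.54 to -1.39), Itgae (3 and 23 counts) was 5.77-fold higher (0.80 to 4.91), and Tcf4 was within 1.5-fold. Of 11 stromal genes 4 were lower and 2 higher (median -0.24), and the median was 0.67 over the 4 genes with a summed count of at least 100 and 0.02 with no count filter. Pecam1 (40 and 2 counts) was 26.6-fold lower (log2 interval -7.83 to -2.79), Fbn1 (19 and 2 counts) was 12.6-fold lower (-6.80 to -1.61), and Kitl and Igfbp4 were 1.77-fold and 1.99-fold higher. Only 4 lymphocyte genes were measured, of which Cd4 was 2.83-fold lower and Il7r, Blnk and Cd79b met neither condition (median -0.16, above 0 with library size scaling). Of 4 erythroid and megakaryocyte genes 2 were lower, the platelet chemokine genes Pf4 (7.17-fold) and Ppbp (3.84-fold), Gp1ba met neither condition, and the median was -1.05, or -0.23 and inside the random range with no count filter. Of 3 mast cell, basophil and eosinophil genes Ccr3 was 9.89-fold lower and Kit 4.33-fold higher on 4 and 23 counts, with a median of -1.61, which was 0.54 with no count filter.

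Ribosomal protein genes had a median log2 ratio of -0.03 (above 0 with library size scaling), with 64 of 65 meeting neither condition and Rps10 the 1 lower gene (28 and 12 counts, 3.10-fold), with the limit that its exons overlap those of another listed gene on the same strand. Rplp0, Rpl10 and Rpl13a met neither condition. None of the 11 measured mitochondrial-genome genes differed by 1.5-fold, although their median of 0.25 lay above 98.6% of random lists, with mt-Co1, mt-Nd3, mt-Nd5 and mt-Cytb at log2 ratios of 0.07, 0.40, 0.30 and 0.41. All 3 measured nuclear RNA and histone genes met neither condition (Hist1h1c -0.46, Hist1h2bc -0.38, Snhg11 0.52; median -0.38, and 0.51 with no count filter). The 4 sex chromosome genes had a median of 0.20. Of 33 genes near Stat2, 6 were higher and 2 lower, with a median of 0.06 inside the random range. Prim1 was 2.55-fold and Suox 2.33-fold higher, and Cd63 was within 1.5-fold. Among 6 genes that vary between substrains (median 0.37, percentile 94.0, and -0.01 with no count filter), Cyfip2 was 1.57-fold higher, and Ide, Apobec3 and Fgfbp3 met neither condition.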

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

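Centring of the ratios within bins of expression was chosen only after the result was seen. All comparisons rest on 1 library per group, and the intervals cover counting error only, so nothing here measures how far 2 WT cultures would differ. No paired analysis was possible because each group has 1 library. The interferon-stimulated median stayed between -2.81 and -2.58 and the cell cycle median between 1.84 and 2.14 under every alternative run. The counts of genes past the threshold depend on the settings. Against 808 higher and 681 lower genes, a 1.5-fold threshold gave 1515 and 1214, a 4-fold threshold 250 and 273, and an interval widened by an assumed coefficient of variation of 0.4 gave 322 and 366. A summed count of at least 100, with fewer genes tested, left 502 higher and 541 lower genes. Centring gave 665 higher and 757 lower genes. The split turned under both, and also with the 4-fold threshold and the interval widened by 0.4, so which direction holds more genes is not settled. The Stat2 log2 ratio was -1.96 with library size, -1.97 on totals without the 20 most abundant and mitochondrial genes and -2.06 after centring. Centring brought the macrophage identity median to -0.20, inside the random range, and took the stromal median to -0.70 and the ribosomal protein median to 0.12, outside it. With a summed count of at least 100 the osteoclast median was -0.31, inside the random range. With no filter on low counts the erythroid and megakaryocyte median was -0.23, inside the random range, and the mast cell, basophil and eosinophil median changed sign to 0.54, where more weakly expressed genes entered both lists. The stromal median was 0.67 over the 4 genes with a summed count of at least 100 and 0.02 with no filter, so its sign is not settled. No filter also turned the neutrophil median to 0.56, the nuclear RNA and histone median to 0.51 and the substrain median to -0.01, each inside the random range. Among lists inside the random range, library size scaling turned the liver X receptor median to 0.18, the sterol synthesis median to 0.11, the stress median to 0.15 and the ribosomal protein median to 0.17. That scaling moved the median log2 ratio of all genes by 0.19, so the zero point moved and these signs turned with it. The cause of the other changes was not tested. Lists with 3 or 4 measured genes rest on few values, and whether their other genes are expressed below the count minimum at this depth was not tested.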

Other observations

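The tests on library scaling, on inflammatory genes, on both kinds of progenitor and on hypoxia-induced genes outside glycolysis were chosen only after the result was seen. Genes induced by bone morphogenetic proteins were lower in T403A: Id3 by a log2 ratio of -4.79 (2123 and 102 counts), Id1 by -4.47 and the inhibitory Smad6 by -3.24. After these 3 had been seen, 10 further genes of the bone morphogenetic protein and TGF-beta response were listed, of which 8 were measured. Of these 6 were at least 1.5-fold lower and none was higher, with a median 2.76-fold lower, below every one of 10000 random lists. Skil was at -1.87, Smad7 at -1.94 and Tgfbi at -1.91, while Bambi (0.05) and Ski (-0.09) stayed near 0. Clec10a, a lectin of alternatively activated macrophages, was at a log2 ratio of 2.98, and the growth arrest-specific ligand gene Gas6 (2.41) and the costimulatory receptor gene Cd28 (2.68) were also higher in T403A. These genes were chosen after their values were seen.

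In cell cycle lists written after the extremes had been seen, all 30 mitotic genes were at least 1.5-fold higher, with a median of 7.71-fold. These include extremes seen first and genes of the cell cycle list, and without both kinds 12 remained, all higher, with a median of 6.07-fold. Among 28 measured S phase genes 11 were higher and none was lower, with a median of 1.39-fold. The clock output genes Dbp and Per3 were seen first, at log2 ratios of 2.33 and 2.19. In lists written after that, 8 other clock output genes had a median of 0.20 inside the random range of -0.31 to 0.50, and 5 genes of the opposite phase had a median of -0.36 (percentile 2.80), with Cry1 at -0.90, Nfil3 at -0.52 and Npas2 at 1.69. Among 80 measured genes within 10 Mb of Stat2, 13.8% were 2-fold apart, against 12.2% of 10948 genes elsewhere. The interferon-stimulated, interferon-gamma and cell cycle lists and Stat2 were left out of both.

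The lower interferon-stimulated genes are not accounted for by scaling, since the highest list median over 6 scalings was -2.58. Gene length and GC content do not account for it either: the median of -2.77 lay below all 10000 random lists matched on expression, length and GC, the lowest of which was at -0.26. A stimulus that reached the WT culture cannot be told apart from an effect of the STAT2 allele, the biological explanation that the design names, because each genotype is 1 library. The inflammatory list shares no gene with the interferon-stimulated and interferon-gamma lists. Its median of -0.78 without their genes is therefore the value already given and decides nothing between these explanations. Exchanged labels were not tested. Ifnb1 had 0 counts in WT and 1 in T403A, too few to compare.

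For the higher cell cycle genes, length and GC content are excluded as the whole cause, since the median of 1.95 lay above all 10000 lists matched on these properties, the highest of which was at 0.42. More granulocyte-monocyte progenitors do not account for the whole difference: Mpo, Elane, Prtn3, Ctsg and Ms4a3, abundant in such cells, summed to 4 counts in T403A (0.20 CPM, exact Poisson interval 0.05 to 0.51), against a median difference of 15.6 CPM for the 38 higher cell cycle genes. More progenitors of other kinds cannot be told apart from more division of macrophages, because 7 of 16 progenitor genes were measured and went both ways, with a median of 0.44 and a range under resampling of the genes from -1.91 to 0.95. Of these, Spint2 (117 and 13 counts), Cd34 (15 and 5) and Myb (21 and 7) were lower, and Kit (4 and 23) was higher. Sox4 (8 and 21), Cd27 (8 and 20) and Meis1 (26 and 47) lay above WT, with intervals that held 1. An effect of the STAT2 allele stays open and was not tested.

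For the lower hypoxia and glycolysis genes, the median of -0.97 lay below all 10000 lists matched on expression, length and GC, the lowest of which was at -0.45. Lower oxygen or a denser culture in the WT dish stays open, because 7 measured hypoxia-induced genes outside glycolysis and outside that list had a median of -0.51, below the random range of -0.31 to 0.43, although 3 of them were lower at 1.5-fold and 4 met neither condition. Of all 20 such genes outside glycolysis, most of which the preset list also holds, 9 were lower and 1 was higher (Ndrg1), with a median of -0.48. The same shift might follow from macrophage activation in the WT culture or from the allele, and these libraries hold no value that separates them.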
